A study of Mus musculus with 3 samples.

How the data were processed

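Mouse bone marrow cells were cultured for 5 days with granulocyte-macrophage colony-stimulating factor, and DC populations were separated by flow cytometry on PDL2, per the labels' protocols. PDL2-negative cells were either left untreated or stimulated with LPS at 100 ng/ml, and PDL2-positive cells were left untreated. The duration of LPS treatment is not given in the sources used here. Total RNA was extracted with silica columns and hybridized with a biotin label. The probe set names are those of the Affymetrix Mouse Genome array that the probe annotation table names, on which each gene is read by 1 or more sets of short oligonucleotides. There were 3 arrays, 1 per group.

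The deposited values are the authors' log2 summaries, with 1 value per probe set and array, as the range of the values shows. The authors' background correction, normalization and summary method is not given in the sources used here. The deposited values ran from 3.19 to 14.82 in PDL2-negative untreated cells, and their medians were 5.59, 5.56 and 5.59 in PDL2-negative untreated, LPS and PDL2-positive samples. The 75th percentiles were 7.90, 7.68 and 7.84. Of the probe sets analysed, 7011 (18.2%) held a single identical deposited value on all 3 arrays, and 1088 of these lay above the floor. The cause of the identical values was not tested. They were not confined to bright probe sets: a pyruvate carboxylase control probe set, left out of those analysed, held 6.06 on all 3 arrays. Separately, a bright probe set can be saturated, which compresses differences near the top of the scale.

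All choices of comparisons, gene lists, size rule and alternatives in the next paragraphs were made before the data were examined, apart from those named as later additions. The rule was to keep the deposited values as they were if the quartiles of the 3 arrays agreed within 0.1 on the log2 scale, and to quantile-normalize them otherwise. The 75th percentiles differed by more, so the values were quantile-normalized over 38533 probe sets, after 13 control probe sets had been left out of 38546. With the deposited values, the median difference over genes above the floor on both arrays was -0.08 after LPS, against 0.04 after quantile normalization. It was 0.00 and 0.02 in the PDL2 comparison, and 0.02 and -0.05 in the comparison of PDL2-positive with LPS-treated cells.

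The annotation table names 34436 probe sets. Of these, 33987 name 1 gene and 449 name several genes, and the latter were used for no gene. A further 4110 probe sets are unnamed there. Symbols were updated through the Entrez gene number in a RefSeq gene table, which held 33800 of those with 1 gene, and the older symbol was kept otherwise. Each of 17886 genes was represented by its probe set with the highest mean signal. The floor was the median of all normalized values, 5.58 on the log2 scale, and lower values were raised to it. A gene entered a comparison if it was above the floor on at least 1 of the 2 arrays. Where it was at the floor on the other array, the fold is a lower bound, given as at least N-fold.

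With 1 array per group there is no estimate of the spread between samples, and no p-value is given. A gene is called higher or lower if it differed by at least 2-fold. The only error measure is technical: the spread between the 2 brightest probe sets of a gene, as a robust SD of the log2 difference, was 0.29 over 4212 genes in the LPS comparison, 0.21 over 4243 genes in the PDL2 comparison and 0.31 over 4121 genes in the third. It says nothing of the variation between cultures or mice. The method was checked on simulated arrays for the PDL2 comparison, with 200 changed genes, noise of SD 0.2 and 10841 genes above the floor. It recovered 98% of genes changed by 1.5 and 100% of those changed by 3 on the log2 scale, and called 1 unchanged gene; in a comparison with no change it called 4 genes. A list of 20 changed genes lay at percentile 100 of the random lists and an unchanged list at percentile 56.9. The simulated changes were placed only in genes with a mean signal well above the floor, and all probe sets of a gene were changed alike. The check therefore does not describe genes near the floor or genes whose probe sets disagree. Its noise also left out variation between cultures or mice, so its 1 and 4 calls give no rate of false calls for the measured arrays.

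There were 26 gene lists: DC maturation, MHC class I and class II presentation, T cell costimulation and polarizing ligands, inflammatory cytokines, inflammatory chemokines, NF-kB target and feedback genes, interferon-stimulated genes, type 2 and IL-4/STAT6-associated genes, DC and myeloid transcription factors, Toll-like receptors and signalling, lectins and uptake receptors, chemokine and migration receptors, cell cycle, glycolysis and hypoxia, oxidative phosphorylation, cholesterol synthesis and efflux, immediate early and stress genes, ribosomal proteins, and markers of macrophages, monocytes, neutrophils and granulocyte precursors, mast cells with basophils and eosinophils, lymphocytes with NK cells, plasmacytoid DCs and erythroid cells. Members at the floor on both arrays were left out of a median, and a median needed 3 members. The position of each median among the medians of 10000 random lists of equal size, drawn from 20 bins of mean expression, describes these arrays and is no test. Another 3 lists were added after the values had been seen.

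The genes named were chosen by rule: Pdcd1lg2 first, the 6 largest increases and decreases among genes above the floor on both arrays, the 3 largest lower bounds in each direction, up to 4 members of each list outside the central 95% of its random lists and 2 members of the others, and a fixed set of DC genes in every comparison. Transcripts known only by clone or locus numbers were passed over. This named 109, 105 and 112 genes in the 3 comparisons, of which 48, 45 and 50 had at least 2 probe sets above the floor. The probe sets differed in sign for 3, 1 and 0 of the genes past 2-fold, and for Tgfb1 the other probe set showed no difference. In the 3 comparisons 9, 12 and 8 genes past 2-fold had a probe set above the floor that differed by less than 2-fold. For 5, 1 and 6 genes past 2-fold and above the floor on both arrays, the lower signal was within the spread between probe sets of the floor, so that the fold is close to a lower bound.

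The relation of the LPS and PDL2 comparisons was set against 100 simulated sets of 3 arrays with no effect, with noise of SD 0.19 per array taken from the spread between probe sets. The alternatives tried were the deposited values with no further normalization, median centring, no floor and no filter, a floor at the 75th percentile (7.80), the mean of a gene's probe sets, size rules of 1.5-fold and 3-fold, the mean in place of the median of a list, and the relation over genes above the floor on all 3 arrays. Leaving out probe sets designed to match more than 1 transcript was added after the data had been seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The raw scanner images were not used here.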

Results

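Gene expression was measured in mouse dendritic cells (DCs) grown from bone marrow over 5 days with granulocyte-macrophage colony-stimulating factor (GM-CSF), a cytokine that drives myeloid precursors to form DCs in culture. The cells were sorted by flow cytometry on PDL2, a ligand of the inhibitory T cell receptor PD-1 that is encoded by Pdcd1lg2. The 3 groups were PDL2-negative cells left untreated, PDL2-negative cells stimulated with 100 ng/ml lipopolysaccharide (LPS, the bacterial ligand of Toll-like receptor 4), and PDL2-positive cells left untreated. Each group had 1 array, so no difference below has a replicate check, no test between groups was possible, and genes are described by size alone. The number of arrays limits the precision. The design states that populations of cultured DCs were compared, and the 3 arrays allow 3 comparisons: LPS against no treatment in PDL2-negative cells, PDL2-positive against PDL2-negative untreated cells, and PDL2-positive untreated against LPS-treated PDL2-negative cells.

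Pdcd1lg2 followed the sort. Its log2 signal was 8.40 in PDL2-negative untreated cells, 9.44 after LPS and 11.73 in PDL2-positive cells, which put it 10.1-fold higher in PDL2-positive than in PDL2-negative untreated cells and 2.06-fold higher after LPS. Across 38533 probe sets, the PDL2-negative untreated array correlated with the LPS array at r = 0.935 and with the PDL2-positive array at r = 0.928, and the LPS and PDL2-positive arrays correlated at r = 0.903. Of 17886 genes, 11230 were above the floor on at least 1 array and 9850 on all 3. Probe sets at the 3' and 5' ends of the actin control differed by 0.15, 0.08 and 0.08 on the log2 scale in the PDL2-negative untreated, LPS and PDL2-positive samples. For Gapdh these differences were 0.08, -0.04 and 0.04.

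**Figure D1:**
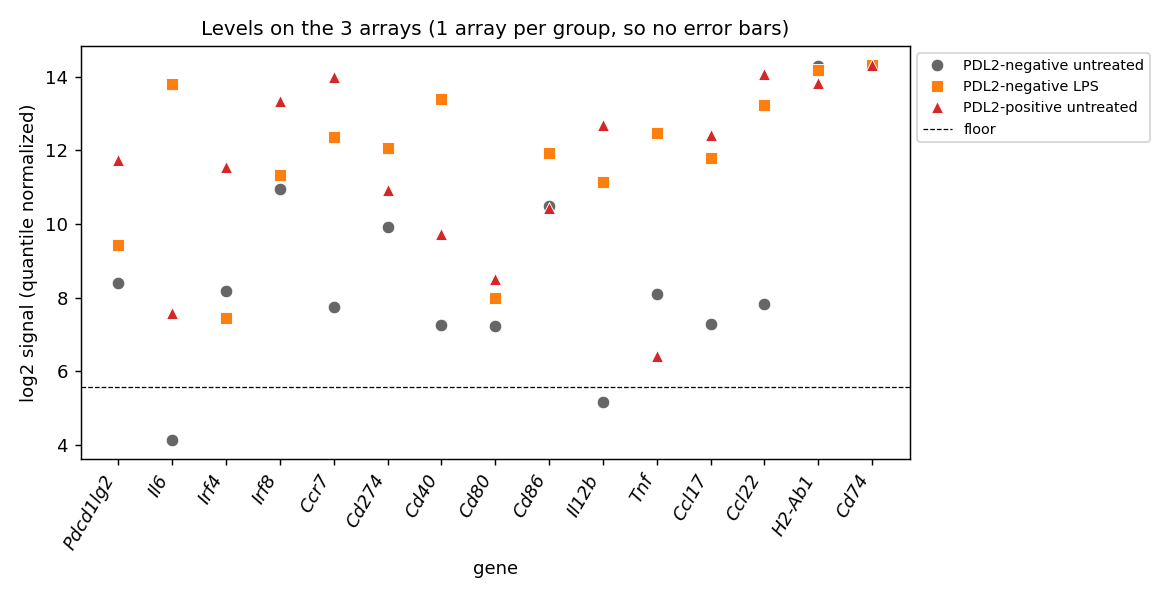
Quantile-normalized log2 signal (vertical axis) of the sorted marker and of the genes named in every comparison (horizontal axis), with 1 point per array and the floor of 5.58 as a dashed line. Il12b lay below the floor in PDL2-negative untreated cells and reached 11.15 after LPS and 12.68 in PDL2-positive cells, whereas Cd74 stood at 14.33 on all 3 arrays.

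The first comparison concerns the response of PDL2-negative DCs to LPS. Cytokine, chemokine and interferon-stimulated genes were higher on the LPS array, and cell cycle genes were lower. Il6, a cytokine of the acute phase response, was at the floor without LPS and at least 296-fold higher with it, and Ptx3, a soluble pattern recognition molecule, was at least 182-fold higher. Among genes above the floor on both arrays, the increases were largest for Cxcl3 (142-fold), Slfn4 (120-fold), the prostaglandin synthase gene Ptgs2 (92.3-fold), Cxcl10 (87.9-fold), Cmpk2 (77.7-fold) and Oasl1 (75.7-fold). Among such genes, the decreases were largest for Scd2, a fatty acid desaturase gene (43.5-fold lower), Fos (33.7-fold), Zfp36l2 (23.4-fold), Tmem86a (22.3-fold), Lpar6 (20.6-fold) and Rgs2 (18.8-fold). For Zfp36l2 the probe sets differed in direction, from -4.55 to 0.07 on the log2 scale. The untreated signal of Slfn4 (5.58) lay just above the floor, so its fold and rank are little more than a lower bound.

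All 33 interferon-stimulated genes measured were higher by at least 2-fold after LPS, with a median log2 difference of 3.62, above all 10000 random lists of the same size and expression. Mx1 was higher by 6.05 and Ifit1 by 5.85 on the log2 scale. Of 20 inflammatory cytokine genes above the floor, 17 were higher and 1 was lower (median 3.62), with Il10 at least 51.5-fold, Il12b at least 47.5-fold and Il1a 47.6-fold higher, the last from an untreated signal close to the floor (5.86). Tnf was 20.7-fold higher. Of 18 inflammatory chemokine genes 12 were higher and 0 lower (median 2.83), among them Ccl5 (47.8-fold) and Cxcl9 (at least 56.6-fold). Of 24 NF-kB target and feedback genes 21 were higher and 0 lower (median 2.51), among them Nfkbiz (20.6-fold) and Tnfaip3 (19.2-fold), which restrain NF-kB signalling or alter its output. Each of these medians lay above all 10000 random lists.

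Of 26 DC maturation genes above the floor, 21 were higher and 0 lower after LPS (median 2.26, above all 10000 random lists). They included Cd40, a receptor for T cell help (70.0-fold), the chemokine gene Ccl22 (42.0-fold), Traf1 (34.9-fold), and Ccr7, the receptor that guides DCs to lymph nodes (24.8-fold), and Ccl17 was higher by 4.53 on the log2 scale. Of 18 genes for T cell costimulation and polarizing ligands, 10 were higher and 2 lower (median 1.31), with Jag1 13.6-fold and Tnfsf9 8.22-fold higher and Vsir 7.65-fold lower. The list also holds ligands that inhibit T cells, among them Vsir and Cd274, so its median does not measure costimulation alone. The log2 difference was 1.44 for Cd86, 0.75 for Cd80 and 2.15 for Cd274, which encodes PD-L1. Other probe sets of Jag1 and Cd86 gave differences as low as 0.79 and 0.17. MHC class I presentation genes had a median of 0.52 with 5 of 14 higher, led by the transactivator gene Nlrc5 (12.6-fold). MHC class II presentation genes had a median of -0.51, inside the central 95% of random lists, with 1 of 13 higher and 4 lower. The higher gene was Marchf1 (10.03 untreated and 11.35 after LPS), whose product removes MHC class II from the cell surface. H2-Ab1 differed by -0.11. The signals of H2-Ab1 and Cd74 lay near the top of the scale, where differences can be compressed.

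Of 31 cell cycle genes above the floor, 20 were lower and 0 higher after LPS (median -1.53, below all 10000 random lists). Mcm7, a subunit of the replicative helicase, was 10.3-fold lower, Birc5 was 8.01-fold lower and Ccna2 6.47-fold lower, and the probe sets of Mcm7 ran from -3.36 to -0.64. Oxidative phosphorylation genes had a median of -0.63, with 3 of 27 lower and 0 higher; for Atp5c1, 1 of these 3, the probe sets differed in direction (-1.29 to 0.13). Glycolysis and hypoxia genes had a median of 0.23 with 8 of 24 higher and 1 lower. The largest increases in this list were those of Nos2 (at least 46.0-fold), Acod1 (35.9-fold) and Pfkfb3 (21.1-fold). Nos2 and Acod1 do not encode enzymes of glycolysis, so their increases are no sign of raised glycolysis. Toll-like receptor and signalling genes had a median of 0.69 with 9 of 24 higher and 3 lower; Tlr3 was higher by 3.33 on the log2 scale, and Tlr4, the LPS receptor, 4.18-fold lower. DC and myeloid transcription factor genes had a median of 0.68 with 11 of 29 higher and 4 lower, among them Batf2, which was 15.7-fold higher, and Klf4, with a log2 difference of -3.46. Irf4 and Irf8 differed by -0.74 and 0.38.

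Among the marker lists for other cells, those for neutrophils and granulocyte precursors, monocytes and plasmacytoid DCs had medians outside the random range after LPS. Neutrophil and granulocyte precursor markers had a median of -1.06, with 9 of 17 lower and 1 higher; Mpo was 3.29-fold lower and Lcn2 13.2-fold higher. Monocyte markers had a median of -0.76 with 3 of 13 higher and 5 lower. Plasmacytoid DC markers had a median of 0.46, with 4 of 11 higher and 1 lower, and Irf7, which is also an interferon-stimulated gene, was 20.5-fold higher. Lectin and uptake receptor genes had a median of -0.76 with 3 of 27 higher and 12 lower, Cd209a being 12.7-fold lower and Clec4e 9.71-fold higher. Macrophage markers had a median of -0.47, inside the central 95% of random lists, with 3 of 22 higher and 5 lower. The medians of mast cell, basophil and eosinophil markers (0.22 over 7 genes) and of lymphocyte and NK markers (-0.38 over 6 genes) were also inside that range. In the latter list the probe sets of Ighm differed in direction (-2.16 to 0.18). Medians inside the range were also found for type 2 and IL-4/STAT6-associated genes (-0.01, or 0.03 with no further normalization and 0.06 with median centring), chemokine and migration receptors (-0.13), cholesterol synthesis and efflux (-0.36, with Ch25h 67.0-fold higher from a signal of 5.81, close to the floor), immediate early and stress genes (0.16, but above the range with no further normalization, median centring or the higher floor) and ribosomal proteins (-0.32).

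By the 2-fold rule, 1009 of 11000 genes above the floor were higher and 1521 were lower after LPS, of which 108 and 166 were at the floor on 1 array. The counts were 746 and 910 with the floor at the 75th percentile, 1660 and 2708 at 1.5-fold, and 581 and 646 at 3-fold. For 1034 genes the brightest probe set was past 2-fold and a second was measured, both above the floor on both arrays. The second had the same direction in 90.4% of them and was also past 2-fold in 60.7%. With the higher floor the neutrophil median was -0.33 and the plasmacytoid DC median 0.05, both inside the random range, the cell cycle median was -0.87, the cytokine median 2.98 and the lymphocyte and NK median -1.61. The mean over monocyte markers was 0.06 and that over glycolysis and hypoxia genes 0.87, with averaged probe sets the oxidative phosphorylation median was inside the random range and the cytokine median was 2.79, and with no floor the latter was 2.93.

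The second comparison concerns how untreated PDL2-positive DCs differed from untreated PDL2-negative DCs. PDL2-positive cells had higher signals for DC maturation genes and lower signals for uptake receptor, macrophage and monocyte marker genes, Toll-like receptors and cell cycle genes. Among genes above the floor on both arrays, the increases were largest for Stat4, a transducer of interleukin 12 signals (89.6-fold), Ccr7 (76.7-fold), Ccl22 (75.6-fold), Ramp3 (70.1-fold), Tnfrsf9 (64.4-fold) and Ndrg4 (62.2-fold). Il12b, the p40 subunit gene of interleukins 12 and 23, was at least 137-fold higher, Serpinb6b at least 92.5-fold and Ceacam15 at least 77.8-fold. Decreases among genes above the floor on both arrays were largest for Clec4a3 (71.1-fold), Sirpb1a (52.0-fold), the growth factor gene Igf1 (51.7-fold), P2ry6 (49.2-fold), the apolipoprotein gene Apoe (48.7-fold) and Rnf128 (47.3-fold). Clec4a3 lay close to the floor in PDL2-positive cells (5.68).

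Of 26 DC maturation genes above the floor, 25 were higher and 0 lower in PDL2-positive cells, with a median log2 difference of 4.15, above all 10000 random lists. Ccl17 was higher by 5.16, Cd40 by 2.48, Cd80 by 1.27 and Cd274 by 1.00, and Cd86, at -0.05, did not differ by 2-fold. NF-kB target and feedback genes went both ways, with 10 of 24 higher and 7 lower (median 0.83); Traf1 was 28.0-fold, Relb 20.2-fold, Birc2 14.6-fold and Rel 10.8-fold higher. DC and myeloid transcription factor genes had a median of 0.75 with 12 of 29 higher and 6 lower. Irf4 was 10.4-fold and Irf8 5.26-fold higher, while Maf and Cebpb, factors of macrophage and myeloid differentiation, were 27.3-fold and 12.3-fold lower. The 5 probe sets of Maf above the floor ran from -4.77 to -0.23 and the 3 of Cd80 from 0.61 to 1.56. Genes for T cell costimulation and polarizing ligands had a median of -0.01 with 6 of 18 higher and 4 lower. They ran from Tnfsf4, which encodes the ligand of OX40, at 5.06 to the inhibitory ligand gene Vsir at -3.45.

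Of 27 lectin and uptake receptor genes, 26 were lower and 1 was higher in PDL2-positive cells (median -4.33). The mannose receptor gene Mrc1 was at least 53.4-fold lower, Mgl2 at least 36.9-fold and the inhibitory Fc receptor gene Fcgr2b 44.0-fold lower. Of 21 macrophage markers above the floor, 18 were lower and 0 higher (median -3.78), among them C1qc (44.6-fold), C1qa (42.3-fold) and the high-affinity Fc receptor gene Fcgr1 (33.4-fold). Of 12 monocyte markers above the floor 11 were lower and 0 higher (median -2.20), among them Itgam (24.3-fold) and Vcan (10.6-fold). Of 23 Toll-like receptor and signalling genes 15 were lower and 1 higher (median -1.89), with Tlr7 at least 30.1-fold, Tlr2 25.7-fold and Cd14 22.1-fold lower, although another probe set of Tlr7 gave -0.69. Each of these medians lay below all 10000 random lists. The fixed lists overlap: 11 of the DC maturation, 9 of the type 2, 6 of the uptake, 5 of the monocyte, 3 of the macrophage and 2 of the Toll-like receptor genes are in another list.

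The medians of the inflammatory gene lists did not follow that of the maturation genes, although members went both ways. Of 33 interferon-stimulated genes 19 were lower and 4 higher (median -1.20, below all 10000 random lists), with Rtp4 at least 20.2-fold, Ifit3 at least 9.86-fold and Oasl2 at least 9.44-fold lower and Mx1 58.3-fold higher. Of 12 inflammatory chemokine genes 7 were lower and 2 higher (median -1.83), with Cxcl2 27.3-fold and Ccl3 14.5-fold lower and Ccl5 40.4-fold higher. Of 15 inflammatory cytokine genes 7 were lower and 4 higher (median -0.98, above 5 of the 10000 random lists). With no floor this median was inside the random range, and Il12b, at least 137-fold higher, was 1 of the 4 higher genes. Tnf was 3.24-fold lower, Il1rn, the interleukin 1 receptor antagonist gene, 8.06-fold lower and Il6 at least 3.98-fold higher. Because the cytokine list holds this antagonist gene, its median in each comparison does not measure inflammation alone. The probe sets of Tgfb1 did not agree on a decrease (-1.95 to 0.00). Of 19 type 2 and IL-4/STAT6-associated genes 10 were lower and 5 higher (median -1.02); Ccl22 and Ccl17 were among the higher and Mrc1 and Mgl2 among the lower genes.

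Of 31 cell cycle genes 21 were lower and 0 higher in PDL2-positive cells (median -1.62, below all 10000 random lists), among them the proliferation marker Mki67 (21.7-fold) and Ccnb2 (at least 12.7-fold). Glycolysis and hypoxia genes had a median just above -1, with 11 of 22 lower and 1 higher, and Hk2 was 9.80-fold lower and Pfkfb3 16.7-fold higher. Oxidative phosphorylation genes had a median of -0.61 with 3 of 27 lower and 0 higher. Medians inside the central 95% of random lists were found for MHC class II presentation (-0.27, with 4 of 13 lower), MHC class I presentation (0.34), chemokine and migration receptors (-0.03), cholesterol synthesis and efflux (-0.25), immediate early and stress genes (-0.09) and ribosomal proteins (0.13). The 4 lower class II genes include Marchf1 (at least 21.8-fold), whose product removes MHC class II from the surface, so its fall is no loss of presentation. Among markers of other cells, those of neutrophils and granulocyte precursors (-0.06), plasmacytoid DCs (-0.31), mast cells, basophils and eosinophils (0.24) and lymphocytes and NK cells (-0.37) were also inside. Of 12 erythroid markers only Car2, which other cells make too, and Epor were above the floor, at 5.36 and 0.02 here and 4.25 and 0.09 after LPS.

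By the 2-fold rule, 1102 of 10926 genes above the floor were higher and 1416 lower in PDL2-positive cells, of which 135 and 227 were at the floor on 1 array; at 1.5-fold the counts were 1939 and 2229, and at 3-fold 587 and 803. Among 960 genes whose brightest probe set was past 2-fold, with 2 probe sets above the floor on both arrays, the second had the same direction in 96.8%. It was also past 2-fold in 70.7%. With the higher floor the medians were 3.36 for DC maturation, -2.96 for uptake receptors, -1.28 for Toll-like receptors, -1.24 for chemokines, -0.61 for interferon-stimulated genes, -0.80 for cell cycle and -1.61 for lymphocytes and NK cells, and with averaged probe sets those for DC maturation, uptake receptors and cell cycle were 3.25, -3.68 and -1.02. With no floor the cytokine median was -0.04 and inside the random range, the type 2 median was -0.19 and the chemokine median -1.16, and the type 2 and oxidative phosphorylation medians were inside the range without probe sets that match more than 1 transcript, the latter also with averaged probe sets.

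**Figure D2:**
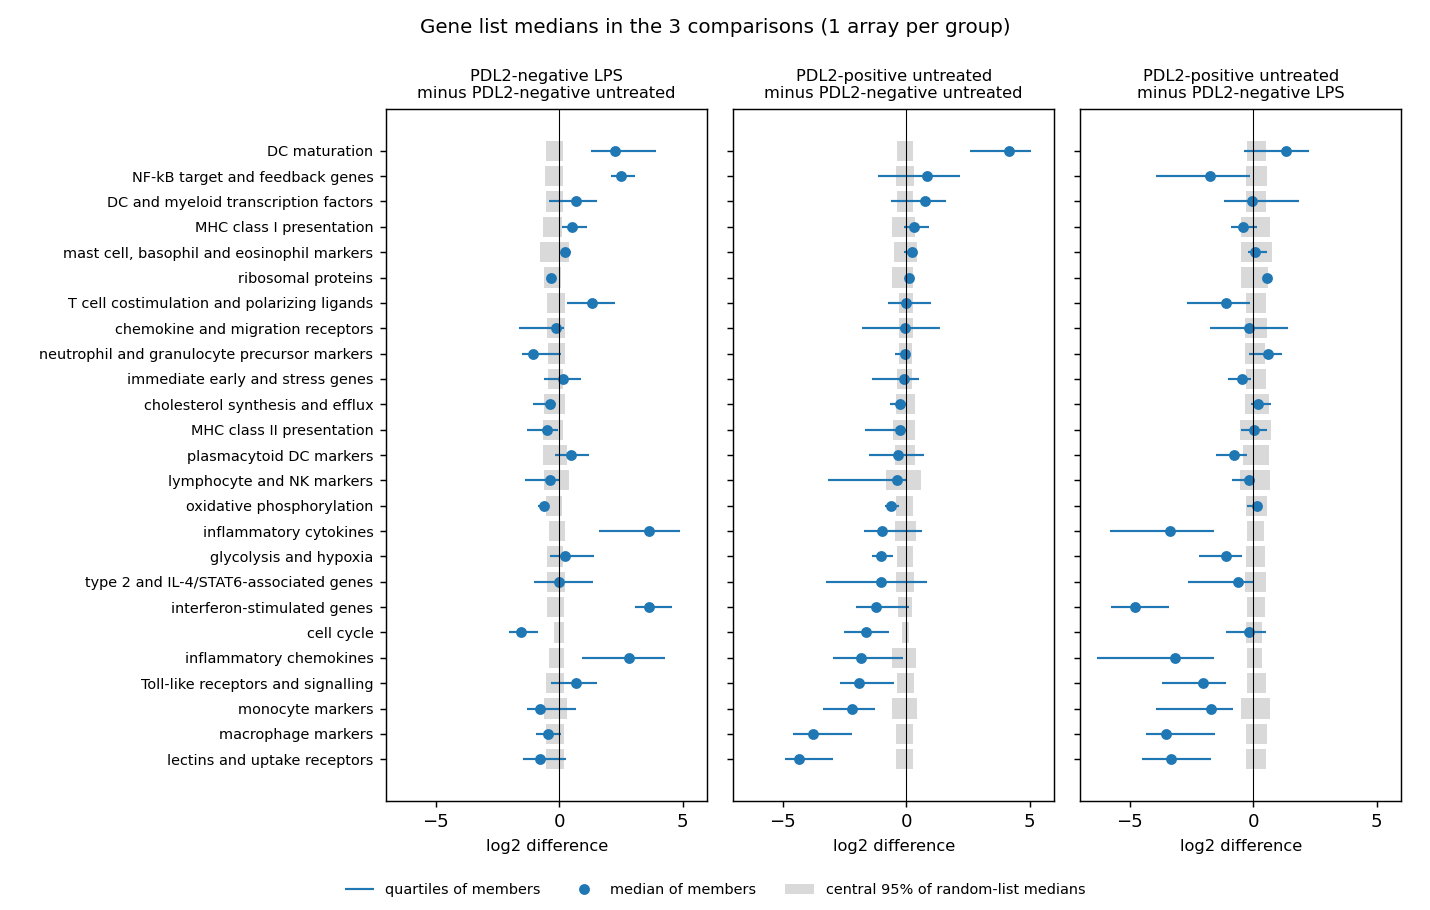
Median log2 difference of the members of each fixed gene list above the floor (points, horizontal axis), with the quartiles of the members (lines) and the central 95% of the medians of 10000 random lists (grey), in the 3 comparisons. DC maturation genes lie to the right of the grey bars in all 3 panels, while interferon-stimulated genes have a median of 3.62 in the first panel, -1.20 in the second and -4.77 in the third.

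The 2 comparisons were set side by side to see which genes differed in both. Both use the same PDL2-negative untreated array, so their differences share its chance values. Of 10696 genes above the floor in both, 291 were higher in both, against 89.1 for independent lists, and 587 were lower in both, against 201 for independent lists. Another 192 genes were higher after LPS and lower in PDL2-positive cells (124.6 for independent lists), and 116 were lower after LPS and higher in PDL2-positive cells (144.1 for independent lists). Across 11230 genes, which are not independent replicates, the differences correlated at r = 0.284 (rho = 0.254). Simulated arrays with no effect gave 0.50 through the shared array alone. Equal noise on every array gives this value whatever the size of the noise, so it is no yardstick for the measured r. The covariance was 0.356 against 0.034 in the simulation, a difference of 0.323. With 1 control array the controls could not be split, and part of the excess may come from the shared array: the simulated noise was taken from probe sets of the same gene and leaves out variation between samples. DC maturation and cell cycle genes lay mostly on the same side in both comparisons, whereas interferon-stimulated genes lay apart. The cell cycle genes with the largest decreases were not the same in both. Mki67 was 21.7-fold lower in PDL2-positive than in PDL2-negative untreated cells, and lower by nearly as much against LPS-treated cells. Mcm7 was 10.3-fold lower after LPS, but higher in PDL2-positive than in LPS-treated cells. Neither decrease was therefore shared.

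**Figure D3:**
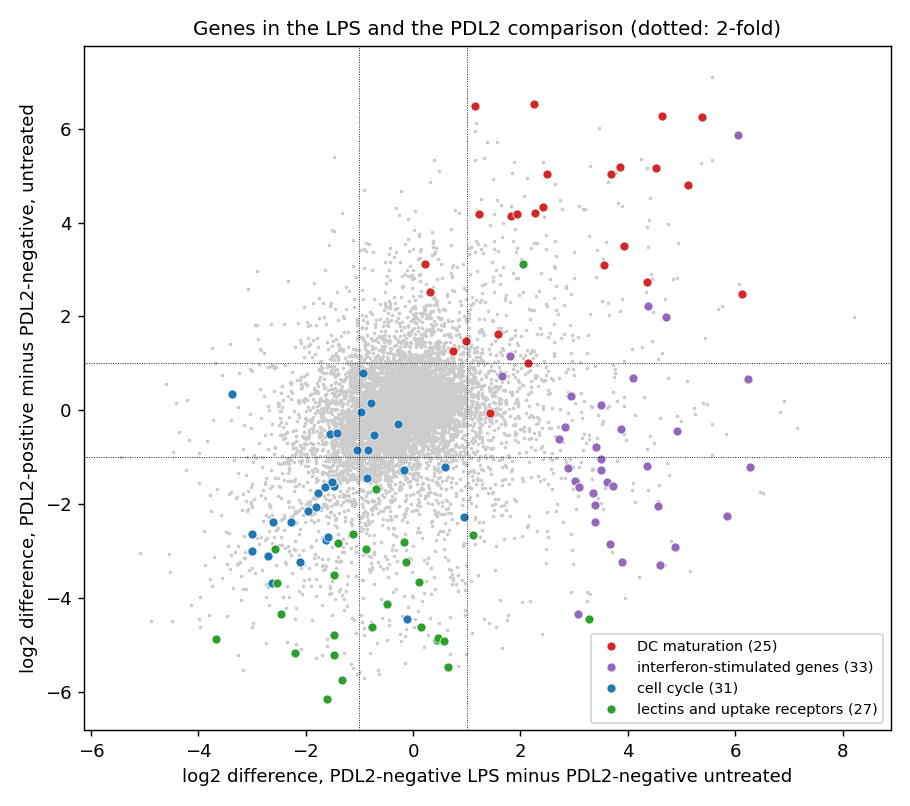
Log2 difference after LPS (horizontal axis) against log2 difference between PDL2-positive and PDL2-negative untreated cells (vertical axis), with 1 grey point for each of 10696 genes above the floor in both comparisons, dotted lines at 2-fold and members of 4 fixed lists in colour. DC maturation genes lie mostly at the upper right, cell cycle genes at the lower left, interferon-stimulated genes at the right and uptake receptor genes at the bottom.

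The third comparison sets untreated PDL2-positive cells against LPS-treated PDL2-negative cells directly, without the shared untreated array. These groups differ in both PDL2 status and LPS treatment, so a difference cannot be assigned to either alone. For each gene it equals the second comparison minus the first, and thus also holds the LPS response with its sign turned. Inflammatory and interferon-stimulated genes were lower in untreated PDL2-positive than in LPS-treated PDL2-negative cells. Uptake and macrophage genes were lower too, and a part of the DC maturation genes was higher. The largest decreases among genes above the floor on both arrays were those of Cxcl10 (294-fold), the acute phase gene Saa3 (244-fold), Clec4e (213-fold), Cmpk2 (178-fold), Cxcl2 (144-fold) and Ccl3 (137-fold). Acod1, which makes itaconate, was at least 385-fold lower, Ptgs2 at least 313-fold and Ifit1 at least 276-fold. Among such genes, the largest increases were those of N4bp2l1 (58.5-fold), Cdkal1 (49.1-fold), Castor2 (46.2-fold), Grasp (41.1-fold), Stat4 (5.32 on the log2 scale) and Mmd (34.0-fold). Cxcl10 and Cmpk2 lay close to the floor in PDL2-positive cells (5.74 and 5.65), and the probe sets of Castor2 ran from 0.56 to 5.53. Ceacam15 was at least 77.8-fold, Ndnf at least 69.6-fold and Gpr65 at least 50.5-fold higher.

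Of 27 DC maturation genes, 14 were higher and 4 lower in PDL2-positive cells (median 1.33, above all 10000 random lists). Serpinb6b was 19.5-fold and Ccr7 3.10-fold higher, whereas Cd40 was 12.5-fold and Cd86 2.80-fold lower, the latter with another probe set at -0.06. Ccl17 and Ccl22 differed by 0.63 and 0.85, less than 2-fold. Irf4 was 17.4-fold and Irf8 4.06-fold higher. Il12b was 2.89-fold higher, and Il6 and Tnf were 74.5-fold and 67.0-fold lower. Of 33 interferon-stimulated genes 30 were lower and 0 higher (median -4.77). Of 20 inflammatory cytokine genes 17 were lower and 3 higher (median -3.35), of 18 inflammatory chemokine genes 14 were lower and 0 higher (median -3.17), and of 24 NF-kB target and feedback genes 13 were lower and 2 higher (median -1.72). Genes for T cell costimulation and polarizing ligands had a median of -1.10 with 10 of 18 lower and 1 higher, led by Tnfsf9 (at least 35.2-fold lower) and Tnfsf4 (9.29-fold higher). The lower genes include that of the inhibitory ligand PD-L1, Cd274 (-1.15).

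Lectin and uptake receptor genes (median -3.32, 24 of 27 lower and 1 higher), macrophage markers (-3.53, 18 of 22 lower and 0 higher), monocyte markers (-1.70, 9 of 12 lower and 0 higher) and Toll-like receptor genes (-2.02, 19 of 24 lower and 1 higher) were below all 10000 random lists. Fcgr2b was 69.0-fold, Fcgr1 106-fold, Cd14 74.3-fold and Axl 44.9-fold lower. Cell cycle genes had a median of -0.17, inside the random range, with 3 of 24 higher and 8 lower. Mki67 had a log2 difference of -4.32, and Mcm7 was 13.1-fold higher, with probe sets from 0.92 to 3.71. Glycolysis and hypoxia genes had a median of -1.09 with 12 of 24 lower and 1 higher. Acod1, which does not encode an enzyme of glycolysis, is among the lower. Neutrophil and granulocyte precursor markers had a median of 0.59 with 6 of 17 higher and 3 lower, and plasmacytoid DC markers a median of -0.78 with 2 of 11 higher and 5 lower. Type 2 and IL-4/STAT6-associated genes had a median of -0.62 and immediate early and stress genes of -0.43, both below the random range. The lists for MHC class I (-0.40), MHC class II (0.04), transcription factors (-0.04), oxidative phosphorylation (0.17), migration receptors (-0.15), cholesterol (0.22), ribosomal proteins (0.54), mast cells, basophils and eosinophils (0.08) and lymphocytes and NK cells (-0.16) were inside it. The sign of the MHC class II median depended on the scaling, at -0.01 with no further normalization and -0.03 with median centring.

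By the 2-fold rule, 1727 of 11042 genes were higher and 1391 lower in PDL2-positive than in LPS-treated cells, with 207 and 231 at the floor on 1 array. With the floor at the 75th percentile the counts were 1099 and 994, at 1.5-fold 2767 and 2047, and at 3-fold 886 and 883. Among 1220 genes whose brightest probe set was past 2-fold, with 2 probe sets above the floor on both arrays, the second had the same direction in 92.0%. It was also past 2-fold in 67.0%. With the higher floor the neutrophil and plasmacytoid DC medians were inside the random range, and those for uptake receptors, macrophages, cytokines, chemokines and interferon-stimulated genes were -2.29, -2.72, -2.63, -2.58 and -4.18. With no floor the macrophage median was -2.87 and the chemokine median -4.03, the means over monocyte and glycolysis lists were -2.46 and -1.73, and the type 2 median was inside the range without probe sets that match more than 1 transcript.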

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

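All alternatives but the one that leaves out probe sets designed to match more than 1 transcript were set before the data were examined. With no further normalization and with median centring, all 84 list medians, 326 named gene values and 10 counts moved by less than their limit, which was the spread between probe sets for medians and genes and 1.5 times for counts. The 84 include the medians of the 3 lists added after the values had been seen. Of the 84 list medians, 52 lay outside the central 95% of random lists, and 49 to 53 did under the alternatives, of 81 with the higher floor, which left fewer than 3 members for the others. Those that moved inside under at least 1 alternative were fatty acid synthesis, neutrophil, plasmacytoid DC and type 2 lists in the comparison with LPS-treated cells, neutrophil, plasmacytoid DC and oxidative phosphorylation lists after LPS, and cytokine, oxidative phosphorylation and type 2 lists in the PDL2 comparison. Those that moved outside were stress, macrophage and lymphocyte lists after LPS, fatty acid synthesis, MHC class I and lymphocyte lists in the PDL2 comparison, and ribosomal proteins in the third. The spread between probe sets leaves out variation between samples, which 1 array per group cannot show. Values near the floor and near the top of the scale understate differences. A looser or stricter size rule changes counts by construction. A higher floor shrinks the difference of a gene or leaves the gene out, and 23 of the 27 list medians that it moved came nearer to 0. For the other changes below the cause was not tested.

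The correlation between the LPS and PDL2 comparisons ran from 0.272 to 0.309, the latter over genes above the floor on all 3 arrays and beyond the 95% Fisher interval over genes. With the floor at the 75th percentile, 910 genes were lower after LPS, 1099 were higher in PDL2-positive than in LPS-treated cells, 188 were higher and 390 lower in both comparisons, 95 were higher after LPS and lower in PDL2-positive cells, and 58 the reverse, which 71 were with probe sets averaged. At 1.5-fold, 1660 genes were higher and 2708 lower after LPS, 1939 higher and 2229 lower in the PDL2 comparison, and 2767 higher in PDL2-positive than in LPS-treated cells. There were then 548 genes higher and 1191 lower in both, and 373 and 388 in opposite directions. At 3-fold, 581 were higher and 646 lower after LPS, 587 and 803 in the PDL2 comparison, and 886 and 883 in the comparison with LPS-treated cells. There were then 141 higher and 255 lower in both, and 74 and 21 in opposite directions.

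The median for monocyte markers after LPS reversed when the mean was taken. Means over list members were 2.64 for DC maturation, 3.16 for cytokine, 0.39 for type 2, -0.17 for macrophage, 0.056 for monocyte, -0.54 for neutrophil, 0.76 for mast cell, -0.71 for lymphocyte, 0.87 for glycolysis and -0.085 for semaphorin and adhesion after LPS. In PDL2-positive against PDL2-negative untreated cells they were 3.78 for DC maturation, -0.89 for MHC class II, -0.16 for cytokine, -1.21 for chemokine, -0.85 for interferon-stimulated, -0.69 for type 2, -3.39 for macrophage, -0.50 for neutrophil, 0.60 for mast cell, -1.33 for lymphocyte, -3.84 for uptake receptor, -0.39 for stress and -0.87 for semaphorin and adhesion. In PDL2-positive against LPS-treated cells they were -0.39 for MHC class II, -3.64 for chemokine, -1.11 for type 2, -3.07 for macrophage, -2.46 for monocyte, 0.042 for neutrophil, -1.73 for glycolysis and -0.82 for stress.

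With no floor, the medians were 2.93 for cytokine and -0.025 for lymphocyte after LPS. In PDL2-positive against PDL2-negative untreated cells they were -0.039 for cytokine, -1.16 for chemokine, -0.19 for type 2, -3.36 for macrophage, 0.00 for mast cell and -0.0024 for lymphocyte. In PDL2-positive against LPS-treated cells they were -2.97 for cytokine, -4.03 for chemokine, -0.21 for type 2 and -2.87 for macrophage. With the higher floor, the medians were 1.02 for costimulation, 2.98 for cytokine, 2.40 for chemokine, -0.33 for neutrophil, -1.61 for lymphocyte, 0.052 for plasmacytoid, -0.87 for cell cycle, 0.66 for stress and -0.72 for fatty acid after LPS. In PDL2-positive against PDL2-negative untreated cells they were 3.36 for DC maturation, 0.33 for costimulation, -1.24 for chemokine, -0.61 for interferon-stimulated, -3.36 for macrophage, -1.68 for monocyte, -1.61 for lymphocyte, -0.80 for cell cycle, -1.28 for Toll-like receptor and -2.96 for uptake receptor. In PDL2-positive against LPS-treated cells they were -2.63 for cytokine, -2.58 for chemokine, -4.18 for interferon-stimulated, -2.72 for macrophage, -0.35 for plasmacytoid, 0.16 for cell cycle, -1.53 for Toll-like receptor and -2.29 for uptake receptor.

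With probe sets averaged, the medians were 0.77 for costimulation, 2.79 for cytokine, -1.05 for cell cycle and -0.47 for fatty acid after LPS. In PDL2-positive against PDL2-negative untreated cells they were 3.25 for DC maturation, -0.91 for interferon-stimulated, -1.02 for cell cycle, -3.68 for uptake receptor, -0.71 for glycolysis, -0.12 for fatty acid and -0.89 for semaphorin and adhesion. In PDL2-positive against LPS-treated cells they were -0.68 for costimulation, -2.90 for cytokine and 0.23 for fatty acid. Without the probe sets of several transcripts, the medians were 0.91 for MHC class I and 0.71 for glycolysis after LPS. In PDL2-positive against PDL2-negative untreated cells they were -0.90 for interferon-stimulated, -0.48 for type 2, 0.97 for transcription factor and -1.78 for monocyte. In PDL2-positive against LPS-treated cells they were -2.24 for NF-kB. Values of named genes moved by more than the spread between probe sets for 30 of 326 with no floor, 0 of them toward 0. The higher floor moved 176 of 315, all toward 0, averaged probe sets moved 95 of 325, 89 of them toward 0, and leaving out probe sets that match more than 1 transcript moved 17 of 270, 14 of them toward 0. Atp5c1 reversed after LPS, to 0.13, without probe sets that match more than 1 transcript.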

Other observations

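The lists of fatty acid synthesis, lysosome, and semaphorin, tetraspanin and adhesion genes, and all tests of explanations in this part, were chosen after the results had been seen. Of 19 genes of fatty acid synthesis and desaturation, 10 were lower and 2 higher after LPS (median log2 difference -1.11, below all 10000 random lists), among them the desaturase genes Scd2 (43.5-fold lower) and Fads1 (18.1-fold lower) and the phosphatidate phosphatase gene Lpin1 (18.5-fold lower), while Dgat2 was higher by 3.32 on the log2 scale. In PDL2-positive against PDL2-negative untreated cells the median was -0.34, inside the central 95% of random lists, with 4 of 19 lower and 1 higher, and against LPS-treated cells it was 0.59, with 6 of 18 higher and 3 lower. With probe sets averaged the median after LPS was -0.47. The median against LPS-treated cells was inside the random range with no further normalization, with median centring, with the higher floor and with averaged probe sets, and that of the PDL2 comparison was outside it under both other scalings. A second probe set of Fads1 gave -0.32, and Lpin1 lay close to the floor after LPS (5.70). The list is not independent of the data, since Scd2, Fads1 and Lpin1 had been seen to differ.

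Of 32 lysosome genes, 17 were lower and 0 higher in PDL2-positive than in PDL2-negative untreated cells (median -1.06, below all 10000 random lists), among them Atp6v0d2, a proton pump subunit gene (15.8-fold lower), and the hydrolase genes Gla (14.5-fold) and Lipa (5.44-fold). After LPS 7 of 32 were lower and 0 higher (median -0.64), and against LPS-treated cells 11 were lower and 1 higher (median -0.55). The list leaves out the lysosomal protease genes Ctsd and Ctsl, which are in fixed lists and had been seen to be lower in PDL2-positive cells (-3.23 and -3.32), so the choice of this group is not independent of the data. Another probe set of Ctsl gave -0.54. Genes of semaphorins, tetraspanins and adhesion went both ways in PDL2-positive cells, with 12 of 18 lower and 3 higher (median -1.29), from Sema7a at 4.11 to the tetraspanin gene Cd53 at -4.27, although their other probe sets gave only 0.70 and -0.28. Their median was -0.41 after LPS, inside the random range with 3 of 18 higher and 5 lower, and -0.94 against LPS-treated cells with 3 of 17 higher and 8 lower.

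Macrophage marker and uptake receptor genes were lower in PDL2-positive than in PDL2-negative untreated cells. Between-array scaling acts alike on genes of like signal. The central 95% of random lists matched on mean signal reached down to -0.40, against list medians of -3.78 and -4.33. This argues against scaling as the whole cause. These positions among random lists were known before the explanation was put, so the comparison restates them and is no new test. Maturation of the kind LPS brings about stays open. The 47 genes of both lists above the floor in the LPS comparison had a median of -0.64 after LPS. The median in the PDL2 comparison, over genes of both lists above the floor there, was -4.04. For 44 of the 47 the log2 difference was lower in the PDL2 comparison than after LPS. That count compares the 2 differences and is not the number of genes lower in PDL2-positive cells. However, 1 array per group gives no spread between samples to set these values against, and the LPS duration is not known here. Cells of macrophage type in the PDL2-negative gate that the PDL2 sort kept out of the other gate remain a candidate explanation too: C1qb and Apoe had log2 signals of 13.65 and 13.11 in PDL2-negative and 9.09 and 7.51 in PDL2-positive cells, and 85.7% of macrophage markers were lower by 2-fold or more, but Siglec1 (-0.08), Fabp5 (-0.20) and Gpnmb (-0.83) were not, and 20 of the markers were above the floor in PDL2-positive cells too. Lower expression within the DCs themselves, a biological difference that the sort names, was not tested and cannot be told apart from a mixture in RNA of whole populations.

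DC maturation genes were higher and cell cycle genes lower in both comparisons that use the PDL2-negative untreated array, so an unusual value on that array may contribute to either pattern. The direct comparison of the other arrays gave a median of 1.33 for DC maturation genes, with 14 of 27 higher and 4 lower. For cell cycle genes it gave -0.17, with 3 of 24 higher and 8 lower. With 1 array per group there is no spread between samples to judge these values against, so the contribution of the shared array cannot be told apart from that of treatment and PDL2 status, which the design names.

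Mx1 was 58.3-fold higher in PDL2-positive than in PDL2-negative untreated cells. A broad rise of interferon-stimulated genes over PDL2-negative untreated cells is argued against by the 32 others above the floor, whose median was -1.22. The median of this list was known before the explanation was put, so the value restates it and is no new test. It is relative to a whole PDL2-negative population, so it cannot exclude an interferon response within PDL2-positive cells. The difference of Mx1 exceeded that of the next highest interferon-stimulated gene by 3.64 on the log2 scale. That the probe set reads another transcript could be checked with a second probe set, but Mx1 has 1 probe set here, so this stays open, as does a change of Mx1 alone in PDL2-positive cells, which was not tested.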
